A study of Homo sapiens with 2 samples.

How the data were processed

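ChIP-seq with an antibody against ZMYND8 was run on chromatin of MDA-MB-231 mammospheres, with 1 library from parental cells and 1 from ZMYND8 knockout cells. Per the labels' protocols, spheres were grown in MammoCult medium, chromatin was prepared with an enzymatic kit and sonicated, and libraries were made with a KAPA Hyper kit. Grouping followed the genotype in the labels. The submitters' processing notes name FastQC 0.11.2, Bowtie2 2.2.3, Picard 1.127, MACS2 2.0.10 and the build hg19, without the role or settings of each. The control library, the calling threshold, duplicate handling and read depth are not given in the sources used here.

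Each deposited list held a position and a score per summit, 1 list per library, with no pooling of libraries. The score is the authors' own −log10 p or q value, and which of these it is was not stated. The lowest score was 1.31 in the parental list, just above the −log10 of 0.05 (1.30), and 1.46 in the knockout list. Scores depend on read depth and on the control, so they were used to describe, rank or filter summits within a list. The same score minimum was also applied to both lists, scores of both are given at some shared sites, and a test in the closing section sets them against each other; none of these is read as a change in binding. Lists called from libraries of different depth can differ in length with no difference in binding, and nothing in the lists allows this to be corrected.

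Positions are 1-based hg19 coordinates. Summits were shared when they lay within 200 bp of each other, and a summit had no partner when none lay within 1000 bp. Counts carry exact Poisson intervals and shares exact Clopper-Pearson intervals, both at 95% and for counting error only. Chance overlap was described by 1000 shuffles within chromosomes and by 1000 moves of 10 to 100 kb. The overlap step was tested on simulated lists of 385 summits, in which 96, 192 and 289 planted shared summits were all recovered. This checks the counting only, since the other simulated summits were drawn with the same 200 bp rule. Runs of summits were defined as 5 or more of the 1000 highest parental summits with gaps of at most 20000 bp. That rule was set after the runs in 15q24.2 and 14q11.2 had been seen.

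The planned annotation classes, gene list tests and motif searches need an hg19 genome and annotation, which were not used here. In their place, hg19 chromosome lengths were taken from GenomeInfoDb 1.38.1, and bands and Giemsa stains from circlize 0.4.16. Transcript models came from example sets shipped with pyranges 0.1.4 (500 transcripts) and GenomicFeatures 1.54.1 (178 transcripts). These software packages are a source outside the deposited data. The first set states no build, but all of the 678 transcripts lie on sequences named in hg19 and within their hg19 lengths. Neither set is known to be a random sample, and 58 of the protein-coding genes are on chromosome 1. Symbols and gene types were matched by identifier to a RefSeq table of assembly GRCh38.p14, none of whose coordinates are given; 666 of the 678 identifiers matched, and 612 transcripts of 408 genes were used. Genes per chromosome were counted in the same table and divided by hg19 lengths.

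A promoter was 1 kb to either side of any sampled TSS. The rule for named summits was fixed before the data were examined. Of the summits it takes, 1 site is not reported here. The rule for sampled genes was added after the lists were seen, but before any summit was set against a gene. It takes every member of the preset lists, the 20 protein-coding genes with the highest scoring promoter summit (ties in alphabetical order), and every sampled gene with a knockout summit. Examples within the added gene groups were chosen after their values were seen. Those groups were written from general knowledge of gene function, not from expression in these cells, after the summits of 30 protein-coding genes had been seen, 29 of which had a promoter summit. Those 30 were left out of the groups, USPL1 only after it had first been placed in the ubiquitin group. Leaving them out lowers the share of a group they would belong to, so each group was also counted with them put in, and ranked with them left out of the random lists. Group counts were ranked among 10000 random lists of sampled protein-coding genes matched on 5 length classes, which describes these libraries only. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No test across libraries was possible. Alternatives covered score thresholds, merging, sharing distances, promoter windows, subsets of summits and each transcript set alone.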

Results

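ZMYND8, a chromatin reader protein with bromodomain, PHD, PWWP and MYND domains, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mammospheres of MDA-MB-231. This established line comes from a triple-negative breast cancer, and mammospheres are floating cultures used to enrich for stem-like cells. The data comprised 2 libraries, 1 from parental spheres and 1 from spheres with a ZMYND8 knockout, both made with the same antibody against ZMYND8. The series title places the work in the regulation of 27-hydroxycholesterol metabolism by ZMYND8. Each library was represented by its list of peak summits on hg19, and read depth was not given in the sources used here. With 1 library per group there is no replicate error, no difference between genotypes has a replicate check, further replicates, if any, were not analysed here, and all intervals below are 95% intervals that cover counting error only.

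The first comparison asked how many sites the antibody recovered with and without the ZMYND8 gene. The parental list held 45924 summits (exact Poisson interval 45504.9 to 46346) and the knockout list held 385 (347.5 to 425.4). The parental list was 119.3 times longer (107.9 to 132.2), and the knockout list came to 0.838% of its length. The targeted gene could not be checked for its own expression, since summit lists carry no transcript levels. With the same score minimum in both lists, the ratio was 60.0 (45.1 to 81.6) at a score of at least 10 and 12.9 (8.44 to 20.7) at 20. A single run of summits in 15q24.2 held 19 of the 48 knockout summits that reached 10 and 19 of the 23 that reached 20. Without it the ratios were 98.7 (68.5 to 147.6) and 69.8 (26.9 to 257.8), the latter from 4 knockout summits.

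Within the parental list the authors' summit score, a −log10 p or q value, had a median of 3.79 and a maximum of 263.6, and 2880 summits (6.27%) reached 10. The 10 commonest score values accounted for 56.5% of the parental summits, so ranks in the lower part of the list were heavily tied. Within the knockout list the median score was 4.65, the maximum was 427.6, and 48 summits (12.5%) reached 10. The scores of the lists were assigned separately and are not set against each other as a change.

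The second comparison asked where the few knockout summits lay relative to the parental ones. Of the 385 knockout summits, 291 (75.6%, exact binomial interval 71.0 to 79.8) had a parental summit within 200 bp, at a median distance of 37 bp among the shared ones. In 1000 shuffles of the knockout summits within their chromosomes the median was 3 shared summits and the maximum 11. When the summits were instead moved by 10 to 100 kb, which keeps the local density of the parental list, the median was 11 and the maximum 25. Within 1000 bp the shared number was 360 of 385, which left 25 knockout summits (6.49%) with no parental summit nearby. In the other direction, 292 parental summits (0.636%) had a knockout summit within 200 bp, and 45368 (98.8%) had none within 1000 bp. When the parental list was limited to its 385 highest summits, the shared share of the knockout list was 24.16% (19.96 to 28.8).

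The ranks of the shared parental summits, examined only after the data were seen, lay high in their list. The 291 parental summits nearest to the shared knockout summits had a median rank of 1244, and 238 of them (81.8%) stood in the highest scoring 25% of the list. Among the 100 highest parental summits 40 (40%, 30.3 to 50.3) had a knockout summit within 200 bp. Outside the 15q24.2 run it was 27 of 85 (31.8%, 22.1 to 42.8). The share was 10.8% (8.83 to 13.0) in the rest of the highest 1000, 1.11% (0.905 to 1.35) in the rest of the highest 10000, and 0.153% (0.115 to 0.199) below that.

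**Figure D1:**
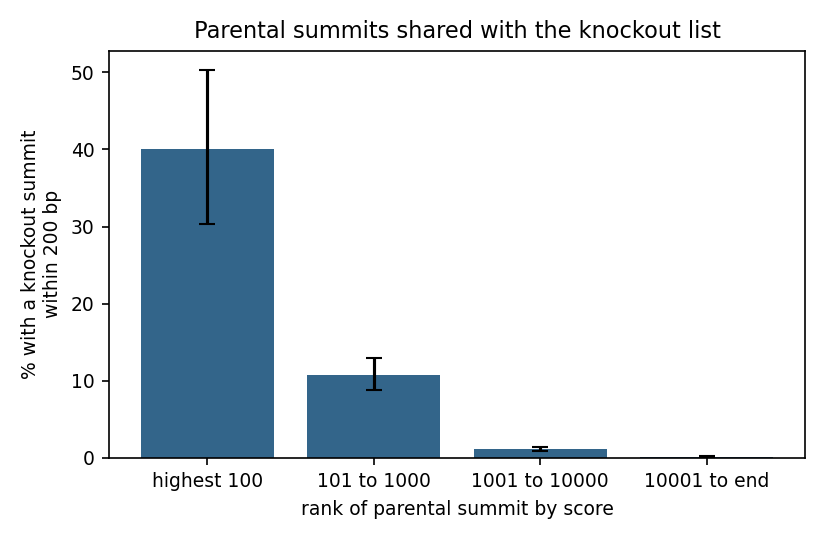
Percentage of parental summits with a knockout summit within 200 bp (vertical axis) by rank of the parental summit score (horizontal axis), with exact 95% binomial intervals as error bars. The share falls from 40% of the highest 100 summits to 0.153% of those ranked below 10000.

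Both lists held a dense run of high scoring summits in 15q24.2. Between positions 75664444 and 75722619 of chromosome 15, a span of 58.2 kb, the parental list held 19 summits with a median score of 71.6. The knockout list held 19 in this span widened by 500 bp at each end, with a median score of 205, and the median distance to the nearest parental summit was 7 bp. In the 100 kb to either side the parental list held 5 summits with a median score of 4.73. Outside this run, high scoring knockout summits included those at 17443598 of chromosome 3 in 3p24.3 (score 160.3) and at 45106882 in 3p21.31 (score 37.1). Their nearest parental summits, within 23 bp, had scores of 49.8 and 150.5. Others lay at 121485275 of chromosome 1 in 1p11.2 (score 35.9) and at 108242 of chromosome 18 in 18p11.32 (score 19.6). For these the nearest parental summits, within 15 bp, had scores of only 3.17 and 2.81. These summits are given by position because a full hg19 gene annotation was not used here.

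**Figure D2:**
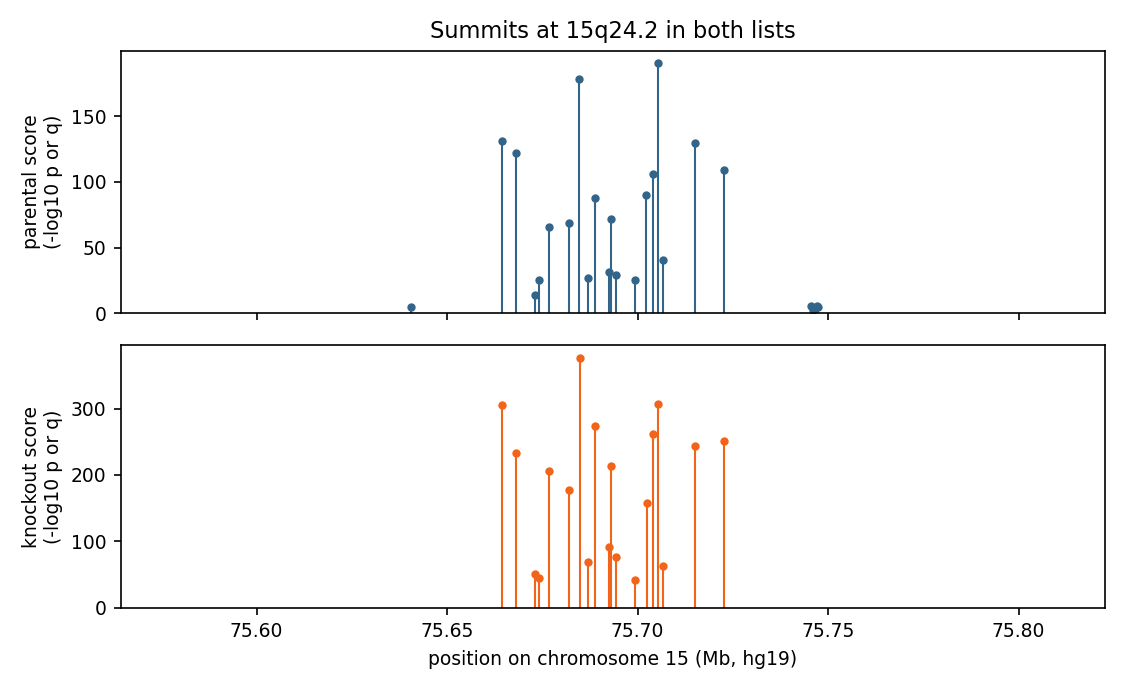
Summits in the 15q24.2 run and 100 kb to either side, with position on chromosome 15 in Mb (hg19) on the horizontal axis and the authors' summit score (−log10 p or q) on the vertical axes, parental above and knockout below, on separate scales. Each vertical line is 1 summit, and each list has 19 in the run.

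Among parental summits with no knockout summit within 1000 bp, a run in 14q11.2 stood highest. It held 8 parental summits between 24584877 and 24592452 of chromosome 14, with a median score of 51.5 and a maximum of 81.1, and no knockout summit. It supplied 5 of the 10 highest summits of this kind. The others lay in 8q24.3 (position 145116028, score 59.7), 12q14.3 (65955689, score 59.1), 2p13.3 (70314071, score 49.7), 6p24.3 (10405010, score 49.2) and 1q24.2 (168195103, score 49.1). The 2p13.3 summit had a knockout summit 1067 bp away. Of the knockout summits with no parental summit within 1000 bp, the highest had a score of 6.98 and lay at 93104 of chromosome 7 in 7p22.3.

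Parental summits were densest on chromosomes 19, 17 and 20. Chromosome 19 held 50.6 summits per Mb, chromosome 17 held 35.4 and chromosome 20 held 29.8, against a median of 15.2 over 23 chromosomes. Across chromosomes of the parental library, which are not independent replicates, summits per Mb and protein-coding genes per Mb had a Pearson r of 0.894 and a Spearman rho of 0.652. Without chromosomes 17 and 19, r was 0.607. Chromosome 20, with 8.52 genes per Mb, was less gene-dense than chromosomes 11 (9.64), 16 (9.45) and 22 (8.79), which held 20.5, 16.9 and 15.4 summits per Mb. Chromosome X stood apart with 1.84 summits per Mb, or 0.336 per protein-coding gene, against 1.69 to 3.75 per gene on the 22 autosomes. Chromosome 20 held 41 knockout summits, 10.6% of the list (7.75 to 14.2), and 4.10% of the parental list. Of the 385 highest parental summits it held 10.9%.

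**Figure D3:**
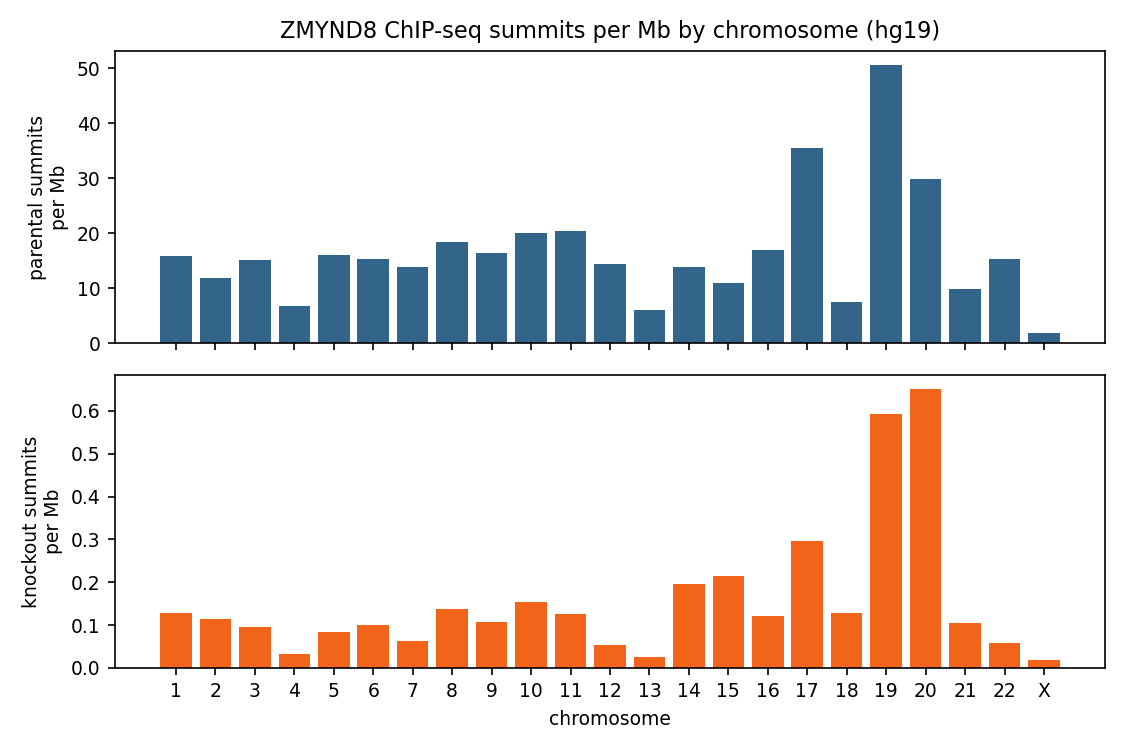
Summits per Mb (vertical axes, on separate scales) on chromosomes 1 to 22 and X (horizontal axis) in the parental list, above, and the knockout list, below. Chromosome 19 has 50.6 parental summits per Mb and chromosome X has 1.84.

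Gene-level results rest on a sample of hg19 transcripts covering 408 genes, 329 of them protein-coding, and describe that sample and not the genome. Of the protein-coding genes, 162 (49.2%, 43.7 to 54.8) had a parental summit within 1 kb of a transcription start site (TSS), and 2 (0.608%, 0.0737 to 2.18) had a knockout summit there. Taking 1 TSS per gene, 47.4% had a parental summit, against a median of 2.43% in shuffles over whole chromosomes and 5.17% when start sites were moved by 10 to 100 kb. Only 62 of the 329 genes (18.8%, 14.8 to 23.5) had a promoter summit from the highest scoring 25% of the list.

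Promoter summits of KEAP1, the adaptor that brings NRF2 to the CUL3 ubiquitin ligase, and of FKBP5, a co-chaperone of the glucocorticoid receptor, had the highest scores among the sampled protein-coding genes. The KEAP1 summit lay at 10613352 of chromosome 19, 95 bp downstream of the TSS, with a score of 18.4. The FKBP5 summit lay at 35696199 of chromosome 6, 161 bp downstream, with a score of 18.2, and the gene body beyond the promoter held 31 further summits. ZNF532, a zinc finger protein known to bind ZMYND8, followed with a score of 16.2 at 56530591 of chromosome 18. CTBP2, a transcriptional corepressor, had 3 promoter summits with a highest score of 13.6 and 26 summits in its body. XPO1, the main nuclear export receptor, had 3 promoter summits with a highest score of 12.4. Others among the 20 highest were CTXN1 (score 15.9), RPP38, a subunit of RNase P (14.4), ANO8 (13.9), HSPA4L (13.6), SCRN1 (13.6), NPHP4 (11.18), ABCF3 (10.02), RANGAP1 (10.02), DCPS (9.92) and A1BG (9.75). The transcription factors PITX1 (10.02) and ETV6 (8.87) also belonged to this set, as did CAMTA1, LEMD2 and PDE4D, each with 8.87. SEPTIN10 and USPL1 had the same score of 8.87 and fell outside the set by alphabetical order. KEAP1 was the only member of these 20 with a knockout summit within 1 kb of a TSS.

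The sampled genes with a knockout summit at a promoter were KEAP1, CUL3 and the long noncoding RNA ENO1-AS1. CUL3, the scaffold of the ligase that uses KEAP1, had a knockout summit with a score of 5.37 and a parental summit with a score of 5.68. The CUL3 summits lay 242 bp (knockout) and 474 bp (parental) from the TSS, too far apart to count as shared. ENO1-AS1 had a knockout score of 13.2 and a parental score of 21.7, and KEAP1 had a knockout score of 3.27.

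Of the 256 genes in 14 lists fixed before the data were examined, 5 were in the sample, so none of these lists could be tested. No member of the cholesterol biosynthesis, sterol sensing or oxysterol lists was among them. ZNF532 and MTA3, a NuRD subunit, came from the list of ZMYND8 partners, and MTA3 had 2 promoter summits with a highest score of 2.50. ALDH1A3, an aldehyde dehydrogenase used as a breast stem cell marker, had 1 promoter summit with a score of 2.93. APOE, a lipoprotein gene from the LXR list, had no promoter summit and 1 in its body. PF4, a platelet chemokine gene from the blood cell markers, had 1 promoter summit with a score of 3.79. None of the 5 had a knockout summit within 1 kb of a TSS.

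Gene groups drawn up after the data were seen differed in their share of promoters with a parental summit. The groups overlapped. UBE3A and USP21, for example, were in the broadly expressed and the ubiquitin groups, and IKZF3 and CRP in the tissue-restricted and the immune groups. Of 63 broadly expressed genes, 43 (68.3%, 55.3 to 79.4) had one, at percentile 99.955 of 10000 random lists matched on gene length, whose median was 31. Examples were GAPDH, a glycolytic enzyme (score 6.70), APP, the amyloid precursor (6.70), and POLR3K, an RNA polymerase III subunit (5.68). Of 54 tissue-restricted genes, 8 (14.8%, 6.62 to 27.1) had a promoter summit, at percentile 0 of lists with a median of 26. Counting any summit from 5 kb upstream to the gene end, 17 of the 54 (31.5%, 19.5 to 45.6) had one, and the percentile stayed at 0. The lung surfactant gene SFTPC, the liver gene CRP and the olfactory receptor gene OR2K2 had none, whereas the lymphoid factor IKZF3 had one with a score of 6.05. Immune and inflammatory genes (7 of 15), zinc finger genes (4 of 8) and ubiquitin system genes (5 of 12) lay at percentiles 42.9, 49.8 and 30.6. These groups leave out genes whose summits had been seen beforehand, nearly all of which had a promoter summit. With such members put in, among them KEAP1, CUL3, USP28 and ZNF532, the counts were 8 of 16, 5 of 9 and 9 of 16, at percentiles 52.6, 62.9 and 71.3. Broadly expressed genes then came to 50 of 70 (71.4%, 59.4 to 81.6) and tissue-restricted genes to 10 of 57 (17.5%, 8.75 to 29.9). With the highest scoring 25% of parental summits, 15 of 63 broadly expressed genes (23.8%) and 1 of 54 tissue-restricted genes (1.85%) had a promoter summit, and the first group then lay at percentile 85.7.

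**Figure D4:**
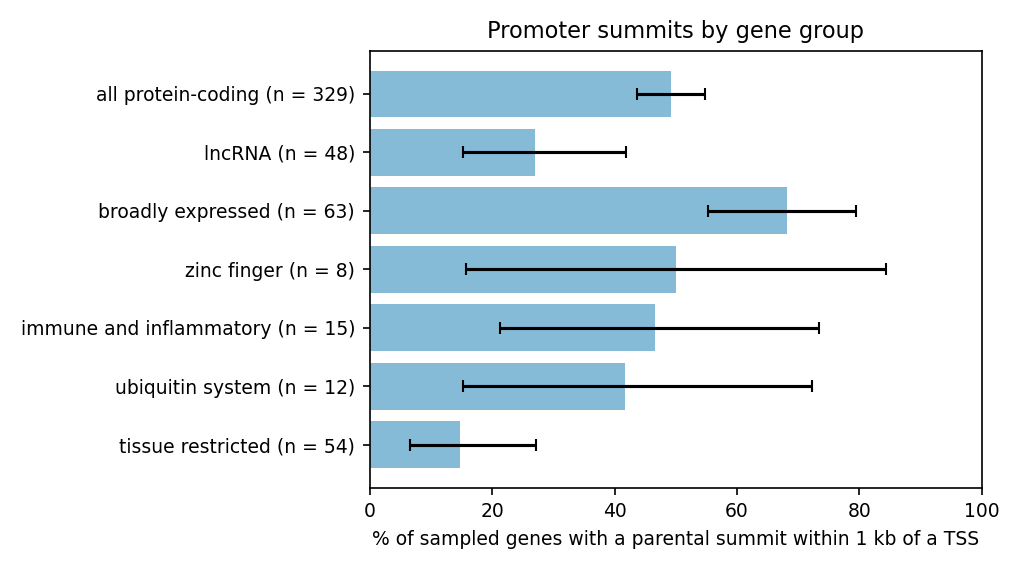
Percentage of sampled genes with a parental summit within 1 kb of a TSS (horizontal axis) for all 329 protein-coding genes, 48 long noncoding RNA genes and 5 gene groups, with exact 95% binomial intervals as error bars. Broadly expressed genes reach 68.3% and tissue-restricted genes 14.8%. Most of the long noncoding RNA genes are on chromosome 1, unlike the protein-coding genes, so these bars are not matched by location.

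Promoter summits lay mostly on the transcribed side of the start site. Counts here are pairs of a sampled protein-coding gene and a parental summit within 1 kb of its TSS. A summit near several genes was counted for each of them, and could lie upstream of a gene and downstream of another. Of 246 pairs, the summit was downstream in 157, upstream in 88 and at the TSS in 1, and within 500 bp in 181 (73.6%). Of the 245 pairs with the summit not at the TSS, it was downstream in 64.1% (57.7 to 70.1), an interval that treats the pairs as independent. The nearest summit of each gene had a median offset of 150 bp downstream.

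**Figure D5:**
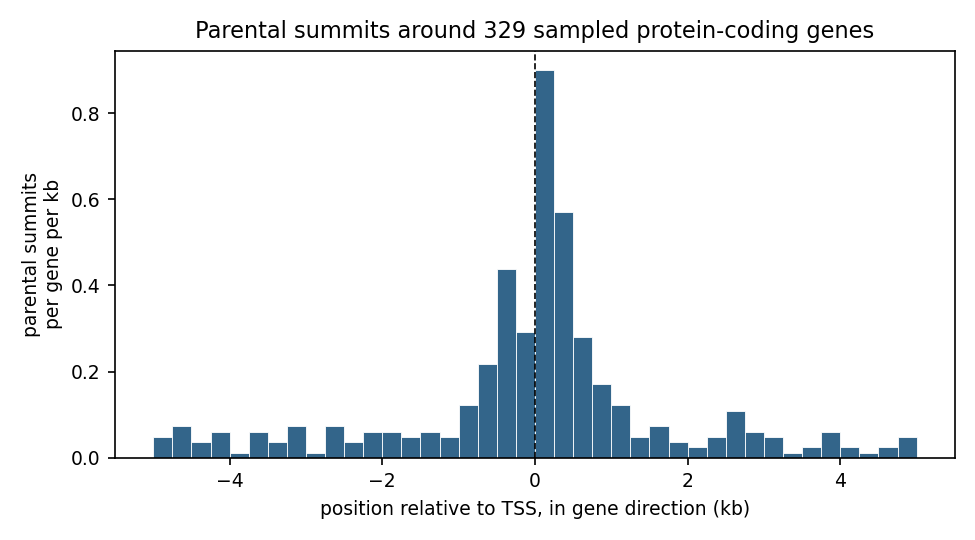
Parental summits per gene per kb (vertical axis) by position relative to the TSS in kb, in the direction of the gene (horizontal axis), in bins over 329 sampled protein-coding genes. The highest bin, 0.900 summits per gene per kb, starts at the TSS and lies downstream of it.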

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

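Settings for promoters, gene groups, chromosomes, bands, offsets, exons and introns, and ranks of shared summits, and those that leave out the 15q24.2 run or heterochromatin bands, were chosen after seeing the data. No paired analysis was possible because each group has 1 library, which allows at most 1 pair. A share was taken to hold when it stayed inside the 95% interval of its main value, and a ratio when it stayed within 1.5 times. Among alternatives for the main results 13 held and 11 did not. Several of the 13 left out few summits or genes and could hardly move, so their number is no measure of robustness. Keeping chromosomes 1 to 22 and X, for example, dropped 7 parental summits and no knockout summit. For the other results the counts were 27 and 5. Some of these 27 changed only the random lists of the gene groups. Their share could not move, so their count among those that held carries no information. With the genes seen first put in, the ubiquitin, zinc finger and immune groups moved from below to above the middle of the random lists (percentiles 71.3, 62.9 and 52.6). With those genes left out of the random lists, the zinc finger and immune groups did so too (57.9 and 56.9). The ratio of list lengths was 60.0 at a score of at least 10 and 12.9 at 20; without the 15q24.2 run, which held 19 of 23 knockout summits at 20, it was 98.7 and 69.8. The shared share of knockout summits was 61.8% within 100 bp, 90.1% within 500 bp, 93.5% within 1000 bp, 24.16% against the 385 highest parental summits and 81.1% for knockout summits above their median score. The distances and the shorter list change the share by construction; for the scores above the median the cause was not tested. Promoters with a summit made up 55.6% within 5000 bp, 18.8% with the highest scoring 25% of summits and 39.5% (15 of 38 genes) with the GenomicFeatures transcripts alone. The first 2 follow from the setting; for the last the cause was not tested. Alternatives fixed in advance for annotation classes, preset gene lists and motifs were not run, for want of an hg19 genome and annotation. Unknown read depth limits every comparison of the lists.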

Other observations

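All tests in this part were chosen after the results they bear on had been seen. Beyond 1 kb of their own sampled TSSs, protein-coding genes held 44 parental summits in exons and 251 in introns. These came to 37.5 and 11.9 per Mb, a ratio of 3.14 (2.23 to 4.34). Promoters of unsampled transcripts and of neighbouring genes were not left out, so the ratio is not shown to lie beyond promoters. Bases were pooled over genes, so long genes with few summits lower the intron density, and exons and introns were not compared within genes. The interval treats summits as independent, although FKBP5 held 31 of them, CTBP2 26 and BCAR1 23. Of 48 long noncoding RNA genes 13 (27.1%, 15.3 to 41.8) had a promoter summit. Most of these 48 genes were on chromosome 1, unlike the protein-coding genes, so the shares are not matched by location. Some shared their summit with a coding gene, as CAMTA1-DT did with CAMTA1. Of 17 microRNA genes 4 had a summit within 1 kb of the model start. These models span 59 to 138 bp, so their starts need not be transcription starts. By Giemsa stain, parental summits numbered 22.8 per Mb in light bands and 4.22 in the darkest bands, which are gene-poor, a ratio of 5.39 (5.15 to 5.63). The knockout list gave 4.68 (2.93 to 7.92). The palest of the stained bands were denser than the light bands in both lists, with 27.5 parental and 0.336 knockout summits per Mb against 22.8 and 0.179. Within 2 Mb of centromere bands lay 26 knockout summits (6.75%, 4.46 to 9.74) and 2.30% of the parental list. Further runs of high parental summits lay in 20q11.22, 20q11.21, 20q13.12 and 5q32. The downstream share among pairs of a gene and a promoter summit, 64.1%, lay outside the central 95% of 10000 random strand assignments, 44.9% to 55.1%.

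The length of the knockout list may reflect loss of ZMYND8 from its sites, a lower yield of the immunoprecipitation, or lower depth. Of the 385 highest parental summits outside 15q24.2, 78.7% (74.3 to 82.7) had no knockout summit within 200 bp, which loss of binding requires but which low yield or depth could also give. With 1 library per group these cannot be told apart. Lower depth alone was examined at knockout summits with a parental summit within 500 bp. The score was higher in the knockout list for 37.5% of 8 in centromere and variable heterochromatin bands, 19 of 19 in 15q24.2 and 12.5% of 320 elsewhere; scores called separately are not on 1 scale, so this decides nothing. Chromosome 20 held 10.9% of the 385 highest parental summits. Sharing of those 385 does not by itself account for that chromosome's share of the knockout list. Of the 292 knockout summits with no partner among them, 9.25% (6.18 to 13.2) were on chromosome 20, against 4.10% of the whole parental list. Sharing of high parental summits ranked below the 385 was not tested.

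The 15q24.2 run may be a signal that does not need ZMYND8, since all 19 of its parental summits had a knockout summit within 500 bp. The 5 parental summits within 100 kb of the run had a median score of 4.73. This was below the 90th percentile of the list (8.01) and above its median (3.79). With 5 summits and an unknown control, the value does not decide whether a copy number gain reaches 100 kb beyond the run. In 14q11.2, 0 of 8 parental summits had a knockout summit within 500 bp. A signal common to both libraries stays open there, because only 40 of the 100 highest parental summits were recovered in the knockout list. DNA from another source in the chromatin or library was not tested for either run.

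Gene density alone does not account for the count on chromosome X, which had 6.46 times fewer summits per gene than the median chromosome. Fewer X copies or X inactivation could lower it, but 26.3% (21.3 to 31.8) of X summits were in the highest scoring 25% of the list, a value that decides neither way. On chromosome 8, the band 8q24.3 held 1236 parental summits, 46.1% of the chromosome's total in 4.42% of its length. Chromosome 8 had 18.3 summits per Mb with this band and 10.3 without it, against 15.2 on the median chromosome. The band was the densest of those of at least 2 Mb, and it was removed from chromosome 8 only. A fall was therefore fixed in advance, since other chromosomes kept their densest bands. The comparison does not decide whether the excess on chromosome 8 comes from 8q24.3. Whether extra copies of 8q24.3 contribute was not tested.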
